A study of Homo sapiens with 16 samples.

How the data were processed

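Expression was measured by RNA sequencing in 16 libraries of BEAS-2B cells, an immortalised human bronchial epithelial line, in 8 groups of 2. Per the labels, cells were kept for 3 weeks in Dulbecco's Modified Eagle's Medium with HgCl2, TCDD, both, acetone or no addition, and total RNA was made into libraries with an Illumina TruSeq RNA kit. Per the submitters' processing notes, the authors aligned reads with STAR 2.4 to GRCh37 (hg19) and used DESeq2, for which no version is given.

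The deposited files hold, for each library, a column of raw counts per gene and a column of RPKM (reads scaled by gene length and by library size). The counting tool, its strand setting and its filters are not stated. Each file has 25411 gene lines on 24 chromosomes, grouped by gene symbol over RefSeq identifiers, of which 6052 have no count in any library; no mitochondrial gene is present. In 1 file, replicate 2 of the low combination, 28 symbols had been turned into dates, so libraries were joined by RefSeq identifier. The deposited counts were used throughout. The deposited RPKM values served only to check the counts: the ratio of RPKM to counts, scaled by library, was 0.998 to 1.027 over 330 genes with at least 3000 counts.

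Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13903, libraries were scaled by TMM, and a quasi-likelihood fit took 1 mean per group with 8 residual degrees of freedom. The common dispersion was 0.0125 (a coefficient of variation of 11.2%) with 4.6 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 by the F test. Standard errors are of the fitted log2 changes. Levels are CPM scaled by TMM, with the SD of 2 libraries. Library totals ran from 7.01 to 41.03 in units of 1e6 counts, so that 3 counts, the limit a count of 0 allows, equal 0.0731 to 0.428 CPM; this covers counting error only.

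There were 16 tests: acetone against untreated; each HgCl2 dose against untreated; each TCDD dose and each combination against acetone; each combination against its TCDD dose and against its HgCl2 dose; the higher against the lower dose in the 3 kinds of treatment; and, at the low and the high doses, the combination minus TCDD alone minus HgCl2 alone plus the untreated control. The labels do not state which control belongs to which treatment. A gene distinct to a combination had to pass in 3 tests in the same direction.

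For gene lists, limma 3.58.1 camera was run on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes and, as an alternative, with an estimated one; p-values were adjusted over the lists of each comparison. The 19 lists hold AHR targets (15 measured), metallothioneins (4), metal transport (9), NRF2 targets (23), heat shock (15), endoplasmic reticulum and integrated stress response (20), p53 targets (16), cell cycle (25), interferon (21), NF-kB and cytokines (19), matrix and mesenchymal genes (23), epithelial genes (16), hypoxia and glycolysis (19), cholesterol (17), immediate early genes (14), airway differentiation (1), other cell types (5), mitochondrially encoded genes (0), and nuclear RNA and histones (10). Lists with at least 3 measured members were tested, which were 17. Counts adjusted over the list alone use a Benjamini-Hochberg adjustment among its members.

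Tests, lists, named genes and most alternatives were fixed before the data were examined. Named genes were 16 sentinels (CYP1A1, CYP1B1, AHRR, TIPARP, NQO1, ALDH3A1, MT1E, MT1X, MT2A, SLC30A1, HMOX1, GCLM, TXNRD1, SRXN1, HSPA1A, HSPA1B); up to 4 called members of each list per test, by size of change; and per test the 10 largest rises and falls among called genes with at least 2 CPM in the higher group and both libraries of 1 group above both of the other, without clone names or pseudogenes. The text names some of these, and some genes are not reported here. The genes common to the TCDD groups were chosen after their values were seen.

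The alternatives were DESeq2 size factors, the Wald test of DESeq2 1.42.0, no count filter, a filter of 5 CPM in 2 libraries, the replicate number as a block, the libraries of the compared groups alone, all 4 control libraries as 1 group, the other control, each library left out in turn, and for lists limma's fry. A correction for GC content (a spline with 5 degrees of freedom per library, on the 93.3% of genes matched to a GC value), alone and with the block, was added after seeing the data, as was a count of distinct genes with the 2 HgCl2 groups exchanged. The fits were tested on simulated data with 100 genes changed by a log2 of 1 and 100 by a log2 of 2, drawn from genes with a mean over 1 CPM. At a log2 change of 1 edgeR recovered 75% for 0.5 µM HgCl2 against control, 80% for 2.5 µM, 78% for the low combination against TCDD, and 43% and 58% for the departures at the low and high doses, with 5 to 12 false calls in these 5. The rates do not cover genes at lower levels. These simulations held no GC trend and gave each gene the same dispersion in every group, so the rates may be too favourable. With an added GC trend edgeR recovered 60% at 2.5 µM HgCl2, with 28 false calls. Tables were read with pandas 2.3.3 and figures drawn with matplotlib 3.10.9.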

Results

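RNA sequencing measured gene expression in BEAS-2B, an immortalised line of human bronchial epithelial cells, after 3 weeks of exposure to mercuric chloride (HgCl2), to the dioxin TCDD, or to both. TCDD is a persistent pollutant that binds the aryl hydrocarbon receptor (AHR), and inorganic mercury reacts with thiol groups of proteins and glutathione. By its title, the series looked for expression changes particular to cells that received mercury and TCDD together. There were 8 groups of 2 libraries each. They were an untreated control, an acetone vehicle control, HgCl2 at 0.5 or 2.5 µM, TCDD at 2 or 10 nM, a low combination (0.5 µM HgCl2 with 2 nM TCDD) and a high combination (2.5 µM HgCl2 with 10 nM TCDD). The labels do not say that the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical only. The experiment number in the labels follows the kind of treatment, so a batch of that kind cannot be told apart from the treatment.

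Total counts per library, in units of 1e6 counts, were 18.6 and 16.9 in the untreated control, 11.9 and 31.5 with acetone, 34.7 and 17.1 at 0.5 µM HgCl2, and 14.6 and 7.01 at 2.5 µM HgCl2. They were 13.3 and 41.03 at 2 nM TCDD, 18.5 and 22.2 at 10 nM TCDD, 9.2 and 16.6 in the low combination, and 25.8 and 20.6 in the high combination. At these depths 3 counts, the limit that a count of 0 allows, equal 0.0731 to 0.428 counts per (CPM), which covers counting error only. The 2 libraries of the high combination lay far apart: the SD over genes of their log2 difference was 0.47, against 0.125 to 0.33 in the other groups. Gene GC content correlated with the deviation of their log2 CPM from the mean of all libraries, across genes, which are not independent. Spearman rho was 0.56 in replicate 1 and -0.65 in replicate 2. Such trends were not particular to this group: rho was 0.31 and -0.61 in the untreated control and 0.38 and 0.64 at 2.5 µM HgCl2. The difference between replicates correlated with GC content at 0.75 in the untreated control and 0.69 in the high combination. Correcting each library for GC content, an alternative chosen after seeing the data, moved the share of higher genes among those called, from 77.9% to 45.4% in the low combination against acetone and from 18.8% to 55.0% between the combinations, so the balance of higher and lower counts below depends on that choice. Below, levels are normalised CPM as mean ± SD (n = 2 per group) and changes are log2 values ± SE. The p-values are Benjamini-Hochberg adjusted over 13903 genes by edgeR unless another test is named. In comparisons with acetone the sizes given are against acetone, also where a gene passed against both controls.

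Some genes cannot be read as single transcripts. Metallothionein genes resemble each other, as do HSPA1A and HSPA1B, and TRIM16 and TRIM16L. Another gene is annotated over part of AHRR (PDCD6), TXNRD1 (EID3), ASNS (MIR7976), DHRS3 (MIR6730), IL24 (FAIM3), BBC3 (MIR3190), HMGA2 (RPSAP52) and TAGLN (LOC100652768). Their values are uncertain to that extent.

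**Figure D1:**
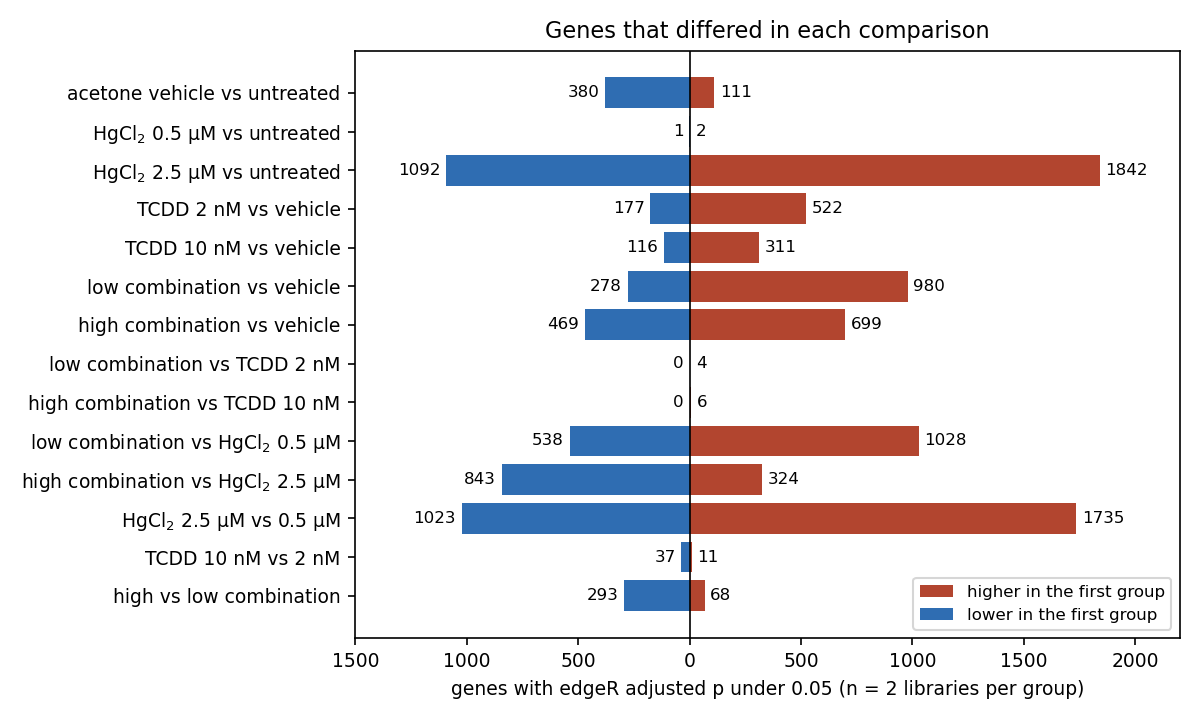
Number of genes called higher (bars to the right) and lower (bars to the left) by edgeR at an adjusted p under 0.05 in 14 comparisons between groups of 2 libraries each. HgCl2 at 2.5 µM against the untreated control had 1842 genes higher and 1092 lower, while the low combination against 2 nM TCDD had 4 higher.

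The first comparison asked how acetone, which the labels call the vehicle control, differed from no treatment. Genes of the integrated stress response, cytokine genes and metallothioneins were lower in the vehicle libraries, and the interferon and cell cycle lists were higher. ASNS, the asparagine synthetase, stood at 20.7 ± 1.83 CPM with acetone and 123 ± 20 CPM without (-2.57 ± 0.16, adjusted p = 1.67e-06). MT1E, a metal-binding metallothionein, stood at 9.52 ± 0.441 against 50.5 ± 0.966 CPM (-2.41 ± 0.12, adjusted p = 3.34e-07). In the other direction COL5A3, a fibrillar collagen, stood at 30.6 ± 2.93 against 1.37 ± 0.179 CPM (4.49 ± 0.21, adjusted p = 1.43e-07).

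Of the 20 genes of the endoplasmic reticulum and integrated stress response list, 12 fell, among them CHAC1 (-2.64 ± 0.23), PSAT1 of serine synthesis (-1.62 ± 0.11) and TRIB3 (-1.25 ± 0.12). By camera, a test of a list against all other genes, the adjusted p was 1.64e-23, and 0.00973 with an estimated correlation. Of 19 measured NF-kB and cytokine genes 11 fell, such as IL6 (-1.09 ± 0.16) and IL1B (-1.05 ± 0.12) (camera 2.55e-16, 0.00318 with an estimated correlation). Of 14 immediate early genes 8 fell, such as EGR1 (-0.97 ± 0.14) and DUSP1 (-1.39 ± 0.15) (camera 5.02e-15, 0.037 with an estimated correlation). The 4 measured metallothioneins fell (camera 1.18e-11, 0.00949 with an estimated correlation), although MT1F at -1 lost its call with any of the 4 libraries left out (-0.87 to -1.28). NPPB (-2.82 ± 0.15), ANKRD1 (-3.38 ± 0.21), STC2 (-2.25 ± 0.08), CPA4 (-2.42 ± 0.1) and VEGFA (-1.04 ± 0.1) also fell. The lipid genes SCD (1.42 ± 0.14), INSIG1 (1.01 ± 0.14) and ABCA1 (2.46 ± 0.38), the matrix gene TGFBI (1.17 ± 0.08) and the antiviral gene OAS2 (1.56 ± 0.21) rose. Of 21 interferon genes 4 rose (camera 3.06e-08, 0.037 with an estimated correlation), the cell cycle list shifted up with none of 25 genes called (camera 0.000899, 0.037 with an estimated correlation), and of 17 cholesterol genes 3 rose (camera 0.000156), with an adjusted p = 0.0914 with an estimated correlation. CYP1A1, the marker of AHR activity, differed by 0.22 ± 0.36 (adjusted p = 0.852), while AHRR, another AHR target, rose by 0.52 ± 0.1 (adjusted p = 0.00818) and 4 of 15 AHR targets fell (camera 0.0892). Of 13903 genes 111 rose and 380 fell. The count of 491 was 223 without control replicate 1, 305 without control replicate 2, 203 without vehicle replicate 1, 161 without vehicle replicate 2, and 1122 after a correction for GC content.

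HgCl2 alone was compared with the untreated control, to ask what mercury does by itself. At 0.5 µM the change was small. NQO1, a quinone reductase (NM_000903, chromosome 16, 69743304 to 69760571, hg19), rose from 72.8 ± 3.09 to 160 ± 6.86 CPM (1.13 ± 0.09, adjusted p = 0.00024). MGST1, a microsomal glutathione transferase, rose by 0.73 ± 0.09 (adjusted p = 0.0195). In all 2 genes rose and 1 fell.

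Of the 23 measured targets of NRF2, the regulator of the antioxidant response, 1 rose by the test over all genes and 11 when adjusted over the list alone (median 0.37, camera adjusted p = 5.44e-22, 0.00388 with an estimated correlation). TXNRD1 and SRXN1, which reduce oxidised thiols, changed by 0.36 ± 0.11 (adjusted p = 0.638) and 0.32 ± 0.07 (adjusted p = 0.29). No stress response gene was called over all genes, 9 of 20 were when adjusted over the list alone (camera 9.16e-12), and the list's adjusted p = 0.0631 with an estimated correlation. The cholesterol list was shifted down (camera 9.4e-08) and the cytokine list up (camera 0.00025), each with an adjusted p = 0.0631 with an estimated correlation. MT1E (0.24 ± 0.11), MT2A (0.27 ± 0.14), SLC30A1 (0.25 ± 0.26), HSPA1A (0.01 ± 0.11) and HMOX1 (0.41 ± 0.15) did not pass the test. DESeq2 called 27 genes in place of 3, edgeR without a count filter 21, with these 4 libraries alone 9, with all 4 control libraries 6, after the GC correction 20 and against the acetone vehicle 771. With any 1 of the 4 libraries left out 1 gene passed, which was NQO1, and 630 genes had an unadjusted p under 0.05.

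At 2.5 µM HgCl2 2934 genes differed from the untreated control. Genes of the response to low oxygen, of cholesterol synthesis and of the interferon response were higher, and heat shock genes were lower. CA9, a carbonic anhydrase of hypoxic cells (NM_001216, chromosome 9, 35673915 to 35681154), stood at 19.9 ± 0.276 against 0.234 ± 0.0917 CPM (6.39 ± 0.5, adjusted p = 1.47e-05). The untreated libraries held only 3 and 5 CA9 counts, so the size of this rise is uncertain. With acetone CA9 stood higher, at 2.78 ± 0.0747 CPM. NDRG1, another hypoxia gene, stood at 391 ± 48.4 against 29 ± 3.12 CPM (3.75 ± 0.23, adjusted p = 4.08e-06). HSPA8, the constitutive HSP70 chaperone, fell from 1890 ± 15.3 to 847 ± 112 CPM (-1.16 ± 0.11, adjusted p = 5.74e-05).

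Of 19 hypoxia and glycolysis genes 13 rose and 1 fell (median 0.78, camera 1.8e-08, 0.0408 with an estimated correlation), among them ALDOC (2.02 ± 0.23) and EGLN3 (1.90 ± 0.29). The secreted glycoprotein STC1 rose by 4.28 ± 0.23. Of 17 cholesterol genes 11 rose and none fell (camera 1.77e-07, 0.0408 with an estimated correlation), with INSIG1 up by 1.62 ± 0.15. Of 21 interferon genes 14 rose (median 0.88, camera 1.8e-08, 0.0408 with an estimated correlation), such as BST2 (1.85 ± 0.34). The members MX2 (1.89 ± 0.25) and OAS1 (1.87 ± 0.28) did not pass against the acetone vehicle. Of 15 heat shock genes 11 fell (median -0.75, camera 7.02e-09, 0.0408 with an estimated correlation), such as HSPA1B (-0.95 ± 0.1) and HSPH1 (-0.97 ± 0.16).

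The NRF2 list moved both ways at this dose, with 5 genes higher and 2 lower (camera 0.5). AKR1C3, an aldo-keto reductase, rose by 2.17 ± 0.31, ABCC3, an exporter of conjugates, by 2.39 ± 0.24 and HMOX1, haem oxygenase, by 0.79 ± 0.15. NQO1 was lower at 55.2 ± 5.57 CPM (-0.41 ± 0.09, adjusted p = 0.0084), a call lost without control replicate 1 (-0.37) or replicate 1 of the treated group (-0.31). Of 4 measured metallothioneins 3 were lower and MT1F was not (camera 0.00853), with an adjusted p = 0.167 with an estimated correlation. MT1E fell by 1.62 ± 0.12 and MT2A by 0.76 ± 0.14, but both were higher against the acetone vehicle, by 0.80 and 0.80. ASNS (-0.95 ± 0.15) and PSAT1 (-0.83 ± 0.1) turned the same way, to 1.62 and 0.79. CDKN1A, the p53-induced cell cycle inhibitor (0.89 ± 0.14), BBC3 (1.25 ± 0.18), DDIT4 (1.79 ± 0.18), MMP2 (1.98 ± 0.2) and the basal cadherin CDH3 (1.73 ± 0.23) rose. CCND1, cyclin D1, fell from 116 ± 26.7 to 19.5 ± 1.14 CPM (-2.56 ± 0.32) and HMGA2, a chromatin protein, by 2.29 ± 0.38, and neither passed against the vehicle. Of 5 measured markers of other cell types 2 rose (camera 0.0541), PDGFRB by 0.68 ± 0.07. TPPP3, the 1 measured gene of airway differentiation, stood at 1.73 ± 0.632 against 0.579 ± 0.0583 CPM (1.47 ± 0.35), a call lost without control replicate 2 (1.37) or 2.5 µM replicate 2 (1.13). Of 9 metal transport genes none passed (camera 0.852), of 16 p53 targets 4 rose (camera 0.0733), and of 10 nuclear RNA and histone genes 3 rose (camera 0.251). In all 1842 genes rose and 1092 fell, and 1936 genes passed in the same direction against both controls, while 41 turned. The count of 2934 was 1946 without control replicate 1, 1576 without control replicate 2, and 1592 with these 4 libraries fitted alone.

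TCDD at 2 nM was compared with the acetone vehicle, to ask what TCDD does by itself. AHR targets rose, CYP1A1 most. CYP1A1, a cytochrome P450 of xenobiotic metabolism (NM_000499, chromosome 15, 75011883 to 75017877), rose from 1.07 ± 0.803 to 14.3 ± 1.05 CPM (3.51 ± 0.27, adjusted p = 1.24e-05). CYP1B1, its relative, rose from 17.1 ± 0.917 to 74.2 ± 1.52 CPM (2.12 ± 0.2, adjusted p = 7.18e-05), and AHRR, the AHR repressor, by 0.64 ± 0.09 (adjusted p = 0.00196). These rises also passed against the untreated control.

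Of 15 measured AHR targets 10 rose (median 1.18, camera 8e-15, 0.000997 with an estimated correlation). Cytokine genes rose too, 11 of 19 with 1 lower (camera 1.05e-15, 0.00182 with an estimated correlation). IL1A (2.33 ± 0.24), IL1B (1.65 ± 0.12) and IL6 (2.04 ± 0.16) did so against both controls, but less against the untreated one. They stood at 6.21, 32.5 and 33.7 CPM, against 2.53, 21.4 and 17.4 CPM untreated and 1.18, 10.2 and 8.1 CPM with acetone. MMP2, a gelatinase (1.96 ± 0.2), the mucin MUC1 (1.10 ± 0.13), ELF3 (1.32 ± 0.2), ABCC3 (2.59 ± 0.26) and DDIT4 (2.25 ± 0.18) rose against both controls. Of 15 heat shock genes 10 fell (camera 7.04e-15, 0.00474 with an estimated correlation), with HSPA1A at -1.06 ± 0.12 and HSPA1B at -0.78 ± 0.1, and TFRC, the transferrin receptor, fell from 666 ± 21 to 259 ± 0.39 CPM (-1.36 ± 0.2). Of 20 stress response genes 13 rose (camera 9.38e-18, 0.0168 with an estimated correlation), with CHAC1 at 3.01 ± 0.23, ASNS at 2.35 ± 0.16 and PSAT1 at 1.42 ± 0.11. Those 3, MT1E (1.30 ± 0.12), VEGFA (1.28 ± 0.1) and KRT17 (1.42 ± 0.2) did not pass against the untreated control. The interferon list shifted up with 3 of 21 genes called (camera 1.05e-05), with an adjusted p = 0.0535 with an estimated correlation. NQO1 changed by -0.22 ± 0.09 (adjusted p = 0.213), and of 13903 genes 522 rose and 177 fell, 257 of them in the same direction against the untreated control and 19 in the opposite one. The count of 699 was 178 without vehicle replicate 1, 159 without vehicle replicate 2, 177 without replicate 1 at 2 nM and 202 without replicate 2. It was 3722 with these 4 libraries fitted alone and 2006 after the GC correction.

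With 10 nM TCDD, CYP1A1 rose to 23.3 ± 2.41 CPM (4.21 ± 0.27, adjusted p = 2.06e-06) and CYP1B1 to 72.7 ± 0.713 CPM (2.09 ± 0.2, adjusted p = 6.61e-05). SERPINB2, a protease inhibitor of stressed epithelium, rose by 2.34 ± 0.25, the cytokine IL24 by 3.00 ± 0.3 and MMP2 by 1.59 ± 0.2, all of them against both controls. The matrix gene EFEMP1 fell from 33.7 ± 1.05 to 10.7 ± 1.16 CPM (-1.65 ± 0.13, adjusted p = 1.21e-05), also against both.

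Of 15 AHR targets 9 rose (median 1.11, camera 1.56e-19, 0.000326 with an estimated correlation). Most other rises held against the vehicle alone. Of 20 stress response genes 12 rose (camera 2.3e-25, 0.00577 with an estimated correlation), with ASNS at 2.83 ± 0.16 and CHAC1 at 2.93 ± 0.23, and the stress gene NUPR1 outside the list rose by 3.09 ± 0.36. The 4 metallothioneins rose by a median of 1.46 (camera 2.44e-12, 0.00536 with an estimated correlation). Of 14 immediate early genes 9 rose (camera 4.22e-16, 0.0266 with an estimated correlation), such as EGR1 (1.17 ± 0.14), and of 19 cytokine genes 10 rose (camera 1.59e-14, 0.00259 with an estimated correlation), such as IL6 (1.54 ± 0.16). Of 17 cholesterol genes 4 fell (camera 4.62e-09, 0.0166 with an estimated correlation), and the desaturase SCD fell by 1.71 ± 0.14. COL5A3 fell from 30.6 ± 2.93 to 0.746 ± 0.225 CPM (-5.37 ± 0.23). Of 25 cell cycle genes 3 fell and none rose (camera 9.27e-06, 0.0112 with an estimated correlation), but against the untreated control none passed (camera 0.35). None of NUPR1, ASNS, CHAC1, MT1E (2.25 ± 0.12), EGR1, IL6, SCD and COL5A3 passed against the untreated control, and MT1E and MT2A turned to -0.16 and -0.16. In all 311 genes rose and 116 fell, of which 49 passed in the same direction against the untreated control. The count of 427 was 152 without vehicle replicate 1, 136 without vehicle replicate 2, 144 without replicate 1 at 10 nM and 177 without replicate 2. It was 59 against all 4 control libraries, 1981 with these 4 libraries alone and 1142 after the GC correction.

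**Figure D2:**
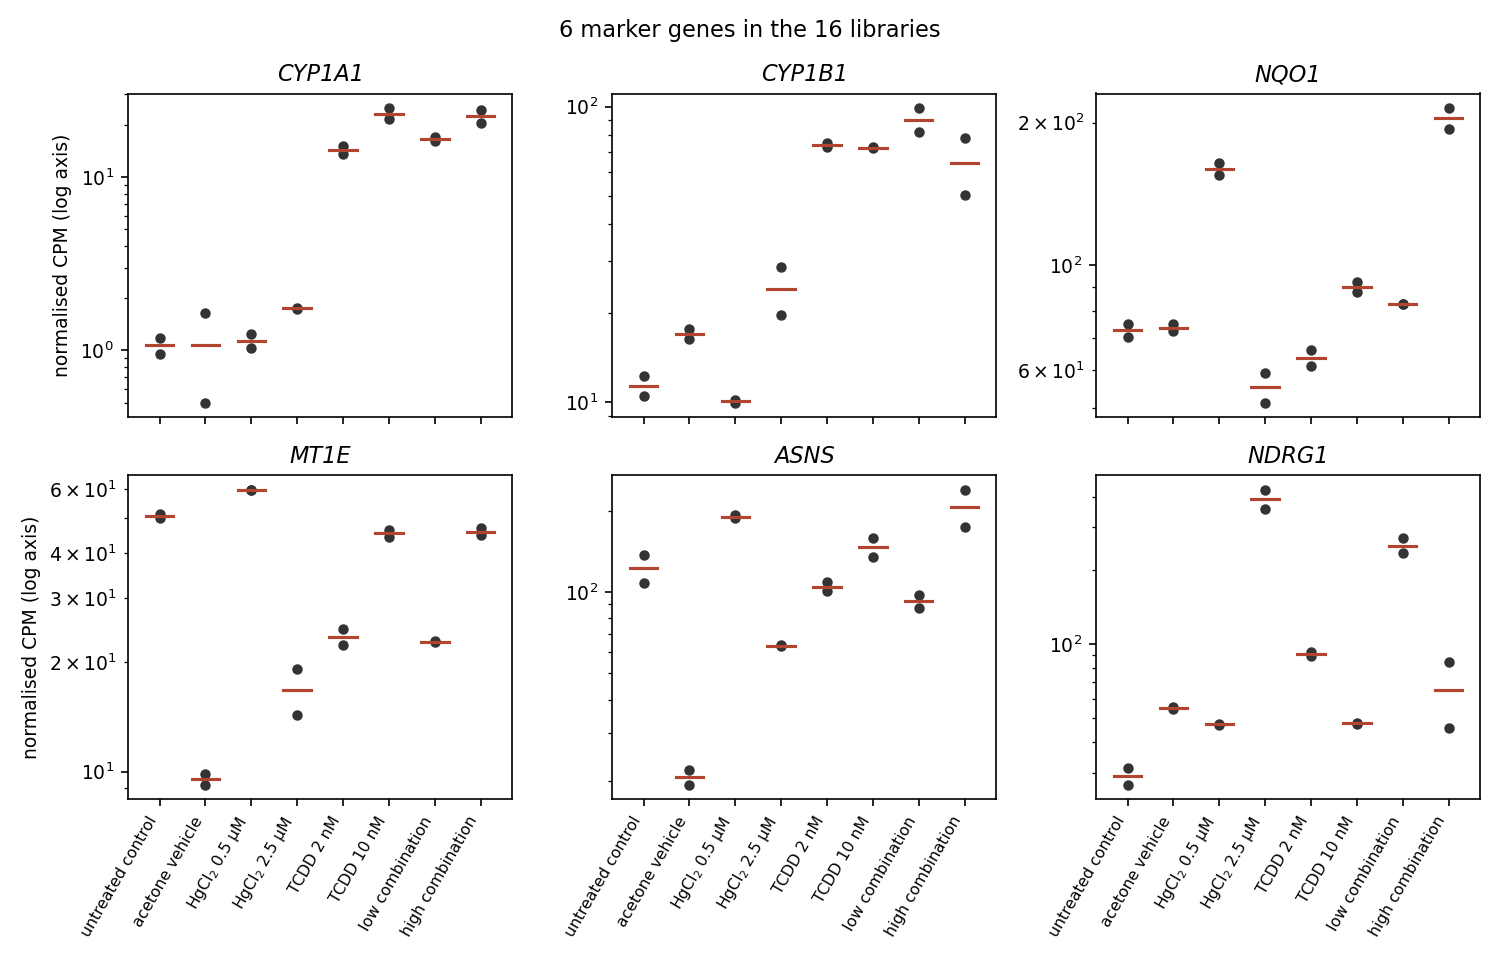
Normalised counts per on a log axis for CYP1A1, CYP1B1, NQO1, MT1E, ASNS and NDRG1 in the 8 groups; points are the 16 libraries and horizontal bars the group means. CYP1A1 had group means of 14.3 to 23.3 CPM in the 4 groups with TCDD and 1.07 to 1.75 CPM in the others, while MT1E and ASNS were lowest with acetone, at 9.52 and 20.7 CPM.

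The low combination was first compared with the acetone vehicle. It raised CYP1A1 to 16.6 ± 0.639 CPM (3.73 ± 0.27, adjusted p = 6.07e-06) and, beside the AHR targets, genes of hypoxia. ANGPTL4, an inhibitor of lipoprotein lipase (NM_001039667, chromosome 19, 8429011 to 8439259), rose from 0.558 ± 0.154 to 10.7 ± 0.0895 CPM (4.36 ± 0.3, adjusted p = 4.36e-06). NDRG1 rose from 55.1 ± 0.668 to 253 ± 24.9 CPM (2.20 ± 0.21, adjusted p = 6.06e-05), CA9 by 2.29 ± 0.35 and STC1 by 3.52 ± 0.21.

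Of 19 hypoxia genes 13 rose (median 0.51, camera 1.87e-10, 0.0172 with an estimated correlation), with VEGFA, the vascular growth factor, at 1.77 ± 0.11. Of 15 AHR targets 10 rose (median 1.26, camera 9.52e-13, 0.0017 with an estimated correlation) and of 19 cytokine genes 9 rose and 1 fell (camera 1.36e-09, 0.00754 with an estimated correlation), such as IL1A (1.88 ± 0.25) and IL6 (1.81 ± 0.17). MMP2 (2.73 ± 0.2), ABCC3 (3.39 ± 0.26), AKR1C3 (2.02 ± 0.32), MUC1 (1.52 ± 0.13), KRT17 (1.89 ± 0.2), CDH3 (1.60 ± 0.22), DDIT4 (2.87 ± 0.19) and DHRS3, a retinaldehyde reductase (4.44 ± 0.5), rose against both controls. Of 15 heat shock genes 11 fell (camera 5.79e-13, 0.00754 with an estimated correlation), with HSPA1A at -0.88 ± 0.12 and HSP90AA1 at -0.79 ± 0.12, and TFRC fell by 1.54 ± 0.2. Of 25 cell cycle genes 7 fell and 1 rose (camera 0.000809, 0.0345 with an estimated correlation), AURKA by 0.67 ± 0.08; against the untreated control the list was not shifted by the test (camera 0.408). Of 16 epithelial genes 5 rose (camera 0.000627), with an adjusted p = 0.0601 with an estimated correlation. The NRF2 list had 6 of 23 genes higher (camera 0.0223), with an adjusted p = 0.198 with an estimated correlation, and NQO1 changed by 0.16 ± 0.09 (adjusted p = 0.3). Of 20 stress response genes 15 rose (camera 6.43e-16, 0.0183 with an estimated correlation), but ASNS (2.16 ± 0.16), CHAC1 (3.26 ± 0.23) and MT1E (1.26 ± 0.13) did not pass against the untreated control. In all 980 genes rose and 278 fell, and 672 of them passed in the same direction against the untreated control. The count of 1258 was 355 without vehicle replicate 1, 386 without vehicle replicate 2, 686 without low combination replicate 1 and 294 without low combination replicate 2. It was 3778 with these 4 libraries alone and 2614 after the GC correction.

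The high combination, also against the vehicle, raised AHR targets and NRF2 targets together. CYP1A1 stood at 22.4 ± 2.78 CPM (4.16 ± 0.27, adjusted p = 1.39e-06) and NQO1 at 204 ± 14.4 against 73.8 ± 1.62 CPM (1.47 ± 0.09, adjusted p = 8.96e-07). AKR1C3 (NM_001253908, chromosome 10, 5136568 to 5149878) rose from 0.635 ± 0.191 to 5.58 ± 1.65 CPM (3.03 ± 0.29, adjusted p = 3.38e-05). IGFBP3, a carrier of insulin-like growth factors, fell by 1.95 ± 0.15. These 4 genes passed against both controls.

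Of 23 NRF2 targets 12 rose (median 0.52, camera 1.17e-11, 0.00863 with an estimated correlation), with TRIM16L at 2.03 ± 0.2 and ABCC3 at 2.34 ± 0.26. Of 15 AHR targets 11 rose (median 1.33, camera 1.33e-15, 0.000763 with an estimated correlation), with SERPINB2 at 2.86 ± 0.24. Of 20 stress response genes 15 rose (camera 5.48e-22, 0.00863 with an estimated correlation). Among them ASNS (3.33 ± 0.16), CHAC1 (3.46 ± 0.23) and DDIT4 (2.49 ± 0.18) rose against both controls, but less against the untreated one. They stood at 206, 67.4 and 96.4 CPM, against 123, 38 and 40.6 CPM untreated and 20.7, 6.15 and 17.1 CPM with acetone. Of 19 cytokine genes 11 rose (camera 1.37e-10, 0.00782 with an estimated correlation), such as IL1A (1.93 ± 0.24). The 4 metallothioneins rose by a median of 1.54 (camera 3.61e-09, 0.00863 with an estimated correlation), but MT1E (2.27 ± 0.12) and MT2A (1.63 ± 0.14) did not pass against the untreated control. Of 17 cholesterol genes 6 fell (camera 2.65e-08, 0.0184 with an estimated correlation), and SCD fell by 2.04 ± 0.14, but by 0.62 against the untreated control. Of 25 cell cycle genes 6 fell (camera 0.000146, 0.0184 with an estimated correlation), AURKA by 0.62 ± 0.08, and the list did not pass against the untreated control (camera 0.133). Of 23 matrix and mesenchymal genes 9 fell and 3 rose (camera 0.000369), with an adjusted p = 0.169 with an estimated correlation. Among them FN1, fibronectin, fell by 1.74 ± 0.18, and outside the list COL5A3 fell to 0.568 ± 0.137 CPM (-5.76 ± 0.23, and -1.28 against the untreated control).

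In all 699 genes rose and 469 fell in the high combination, of which 279 passed in the same direction against the untreated control. The count of 1168 was 4947 without high combination replicate 2, 683 without its replicate 1, 376 without vehicle replicate 1 and 328 without vehicle replicate 2. With these 4 libraries alone 29 genes passed, and of the genes just named AKR1C3, TRIM16L, ABCC3, IL1A, AURKA and FN1 did not. The count was 568 against the untreated control, 576 against all 4 control libraries and 2380 after the GC correction.

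**Figure D3:**
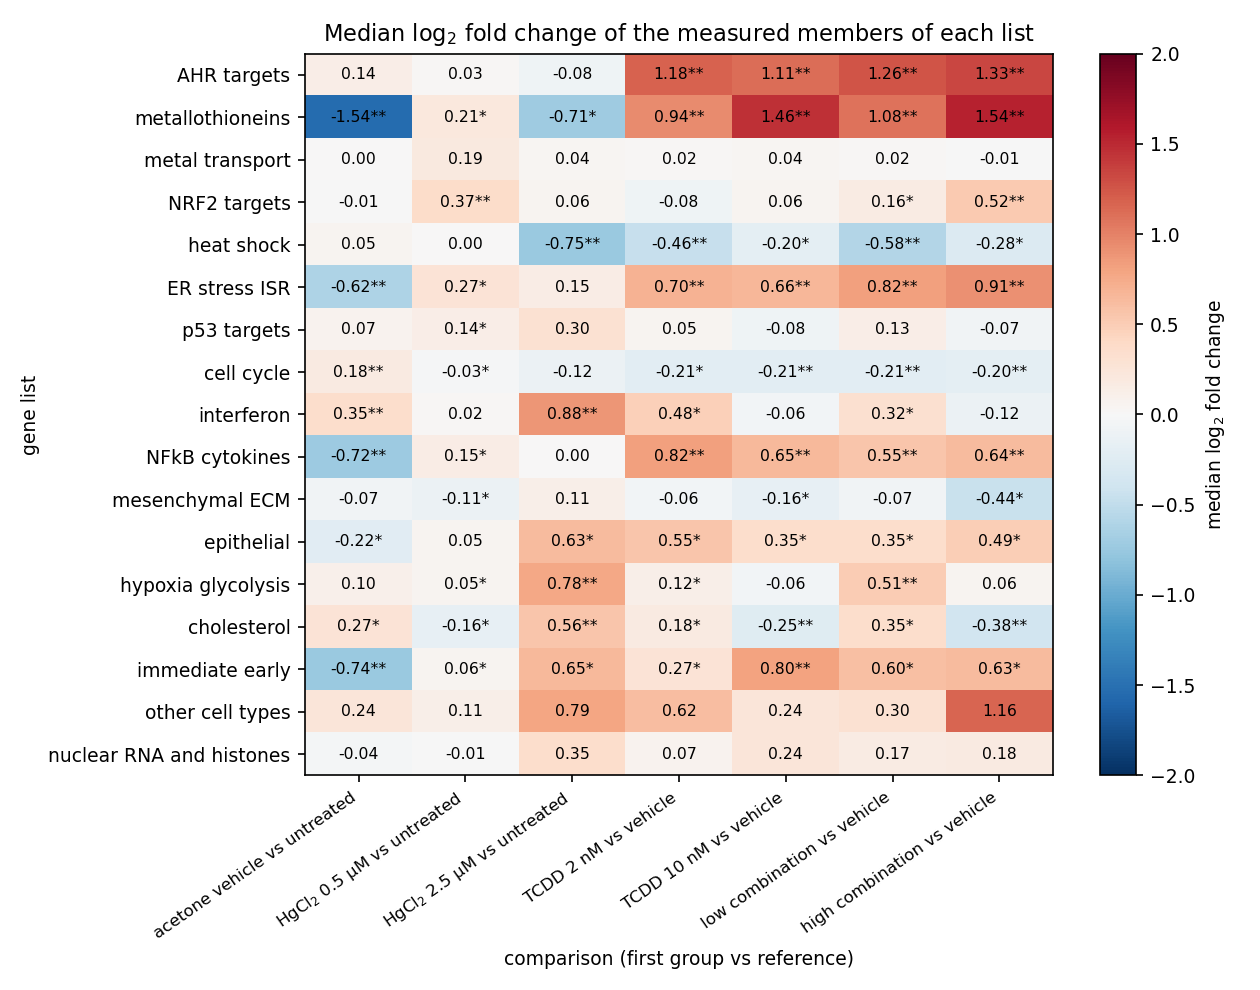
Heat map of the median log2 change of 17 gene lists (lines) in 7 comparisons against a control (columns). One star marks a camera adjusted p under 0.05 with the preset correlation of 0.01, 2 stars also with an estimated correlation; the AHR targets carry 2 stars in the 4 TCDD groups against acetone, with medians of 1.11 to 1.33.

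Genes that passed in all 4 TCDD-containing groups, and against each of the controls, numbered 29. The 27 higher ones included CYP1A1 (at least 3.51), CYP1B1 (at least 1.91), DHRS3 (at least 2.81), MMP2 (at least 1.52), SERPINB2 (at least 1.22), ALDH1A3, an enzyme of retinoic acid synthesis (at least 1.10), STC1 (at least 1.08), TIPARP, an AHR-induced ADP-ribosyltransferase (at least 0.79), KLF9 (at least 0.88) and MUC1 (at least 0.58). The 2 lower ones were IGFBP3 and TAGLN, a smooth muscle cytoskeletal gene, with falls of at least 0.54 and 0.51. Of these genes, 19 of the 27 higher and 1 of the 2 lower also passed in the same direction at 2.5 µM HgCl2 without TCDD, against both controls. The comparisons of several groups with 1 control share its libraries, which cannot be split, and those of 1 group with both controls share the libraries of that group, so part of these overlaps may come from shared libraries. In 20 simulations without any change, at most 1 gene passed against both controls in any group. The simulated libraries held no real or technical shift, so they cannot show how much overlap shared libraries give when there is one. For 1 group against both controls, independent lists of these sizes would share 279 higher genes at 2.5 µM HgCl2, where 1319 were found, 18.3 at 2 nM TCDD (191), 1.68 at 10 nM (31), 73.4 in the low combination (531) and 12.2 in the high one (156). The 29 genes were 10 or 18 without control replicate 1 or 2, 6 or 7 without vehicle replicate 1 or 2, 13 or 14 without 2 nM replicate 1 or 2, 9 or 10 without 10 nM replicate 1 or 2, 17 or 15 without low combination replicate 1 or 2, and 38 or 77 without high combination replicate 1 or 2. They were 4 with the libraries of each comparison alone, 16 with the block, 40 by DESeq2, 40 without a count filter and 93 after the GC correction (54 higher and 39 lower). The same recounts of genes against both controls, by the libraries alone and after the GC correction, gave 1163 and 2473 in place of 1936 at 2.5 µM HgCl2, 607 and 906 in place of 257 at 2 nM TCDD, 88 and 152 in place of 49 at 10 nM, 1107 and 1416 in place of 672 in the low combination and 5 and 650 in place of 279 in the high one. With 1 library left out, the genes that passed against both controls numbered 973 (vehicle replicate 1) to 1505 at 2.5 µM HgCl2, 46 (replicate 1 at 2 nM) to 190 at 2 nM TCDD, 13 (vehicle replicate 1 or 10 nM replicate 1) to 32 at 10 nM, 106 (low combination replicate 2) to 407 in the low combination, and 74 (control replicate 1) to 2473 (high combination replicate 2) in the high one.

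The series title concerns co-exposure, so each combination was compared with its own TCDD dose, to ask what mercury added. On 2 nM TCDD, 0.5 µM HgCl2 raised 4 genes and lowered none. ANGPTL4 rose from 0.767 ± 0.143 to 10.7 ± 0.0895 CPM (3.73 ± 0.27, adjusted p = 8.34e-05) and STC1 (NM_003155, chromosome 8, 23699434 to 23712320) from 2.34 ± 0.275 to 8.89 ± 1.43 CPM (1.91 ± 0.17, adjusted p = 0.000564). NDRG1 rose by 1.47 ± 0.21 (adjusted p = 0.0308) and IGFN1, a muscle filament protein gene, by 0.71 ± 0.1 (adjusted p = 0.0284). NDRG1 lost its call without any 1 of the 4 libraries (1.36 to 1.56), and IGFN1 without either 2 nM library (0.71 and 0.71) or low combination replicate 1 (0.58). Of 19 hypoxia genes 1 rose over all genes and 13 when adjusted over the list alone (median 0.42, camera 2.9e-21, 0.00612 with an estimated correlation). The NRF2 list, with 5 of 23 higher when adjusted over the list alone (camera 5.08e-07), had an adjusted p = 0.0604 with an estimated correlation. CYP1A1 differed by 0.22 ± 0.21 and MT1E by -0.04 ± 0.12. The count of 4 was 2 without low combination replicate 1 or either 2 nM library and 3 without low combination replicate 2; it was 13 by DESeq2, 7 with no count filter, 31 with these libraries alone and 2 with replicate numbers as a block. Beside the 0 genes lower, DESeq2 called 1 lower, and 602 genes had an unadjusted p under 0.05 in either direction.

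On 10 nM TCDD, 2.5 µM HgCl2 raised 6 genes, of which 4 are NRF2 targets, and lowered 0 (5 by DESeq2, and 595 genes at an unadjusted p under 0.05 in either direction). NQO1 rose from 90 ± 3.15 to 204 ± 14.4 CPM (1.18 ± 0.09, adjusted p = 0.000136), AKR1C3 from 1.23 ± 0.305 to 5.58 ± 1.65 CPM (2.17 ± 0.26, adjusted p = 0.0115), TRIM16L by 1.5 ± 0.2 (adjusted p = 0.0196) and TRIM16, a ubiquitin ligase, by 1.14 ± 0.16 (adjusted p = 0.0292). IGFN1 (0.66 ± 0.09) and MGST1 (0.65 ± 0.09) each had adjusted p = 0.0319. Of the 23 NRF2 targets 14 rose when adjusted over the list alone (median 0.47, camera 4.12e-33, 0.000902 with an estimated correlation), while the stress response list (camera 1.27e-07) had an adjusted p = 0.294 with an estimated correlation. SRXN1 changed by 0.45 ± 0.07 (adjusted p = 0.0797), HMOX1 by 0.54 ± 0.15 (adjusted p = 0.653), CYP1A1 by -0.05 ± 0.2 and MT1E by 0.02 ± 0.11. Without either 10 nM library 1 gene passed, NQO1; without high combination replicate 1 there were 10 and without replicate 2 1624, and with these 4 libraries alone edgeR called 0. DESeq2 called 22, the fit without a count filter 16, the GC correction 11 and the replicate block 2.

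A gene was counted as distinct to a combination when it differed from the vehicle, from its TCDD dose and from its HgCl2 dose in the same direction. ANGPTL4, STC1, NDRG1 and IGFN1 met this in the low combination, and NQO1, TRIM16, TRIM16L, MGST1 and IGFN1 in the high one. The low count of 4 was 2 without replicate 1 of the low combination or any 1 vehicle, 0.5 µM or 2 nM library. The high count of 5 was 1 without any 1 vehicle or 10 nM library, 3 without either 2.5 µM library, 8 without high combination replicate 1 and 307 without its replicate 2. DESeq2 counted 10 and 15. With the 2 HgCl2 groups exchanged, 1 gene (IGFN1) was left in the low combination and 2 (IGFN1 and TRIM16L) in the high one. STC1 and NDRG1 stood at 9.73 and 391 CPM at 2.5 µM HgCl2 alone against 8.89 and 253 CPM in the low combination, and MGST1 and NQO1 at 148 and 160 CPM at 0.5 µM alone against 153 and 204 CPM in the high one.

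Against the same dose of HgCl2, the question is what TCDD with its solvent added. Acetone was taken as that solvent, so in both combinations the effects of TCDD and acetone cannot be told apart here. In the low combination CYP1A1 rose by 3.90 ± 0.27 (adjusted p = 5.66e-06), CYP1B1 by 3.17 ± 0.21, AHRR by 1.68 ± 0.1, MMP2 by 2.41 ± 0.19 and BMF, a pro-apoptotic gene, by 2.73 ± 0.17. NQO1 fell from 160 ± 6.86 to 82.7 ± 0.0523 CPM (-0.95 ± 0.09, adjusted p = 5.64e-05), and CCND1 (-1.95 ± 0.31), MT1E (-1.38 ± 0.12) and TIE1 (-2.59 ± 0.25) fell. With acetone alone CCND1 (29.8 against 116 CPM untreated), MT1E (9.52 against 50.5) and TIE1 (1.02 against 3.3) were also lower, and NQO1 was not (73.8 against 72.8). Of 17 cholesterol genes 10 rose (camera 1.12e-12, 0.0144 with an estimated correlation), of 21 interferon genes 10 rose (camera 6.96e-11, 0.0162 with an estimated correlation), and of 15 heat shock genes 11 fell (camera 6.27e-12, 0.0144 with an estimated correlation). In all 1028 genes rose and 538 fell. The count of 1566 was 411 and 526 without replicate 1 or 2 at 0.5 µM, 849 and 431 without replicate 1 or 2 of the low combination, 4355 with these libraries alone and 2631 after the GC correction.

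In the high combination, against 2.5 µM HgCl2, CYP1A1 rose by 3.68 ± 0.28 (adjusted p = 1.39e-05), SERPINB2 by 4.10 ± 0.3 and NQO1 from 55.2 ± 5.57 to 204 ± 14.4 CPM (1.90 ± 0.09, adjusted p = 3.96e-07). Hypoxia genes were lower: STC1 fell by 2.55 ± 0.18, NDRG1 by 2.58 ± 0.21 and CA9 by 2.68 ± 0.34. Of 19 hypoxia genes 11 fell and of 17 cholesterol genes 9 fell (both camera 2.2e-15, 0.00633 with an estimated correlation). Of 15 heat shock genes 10 rose (camera 1.34e-09, 0.0151 with an estimated correlation), and of 23 NRF2 targets 10 rose and 1 fell (camera 9.94e-08, 0.0272 with an estimated correlation). In all 324 genes rose and 843 fell. The count of 1167 was 574 without 2.5 µM replicate 1, 3749 without high combination replicate 1 and 1947 after the GC correction, and 11 with these libraries alone, where NDRG1 and CA9 did not pass.

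Between doses, 2.5 µM against 0.5 µM HgCl2 raised 1735 genes and lowered 1023. CA9 (4.21 ± 0.38) and NDRG1 (3.05 ± 0.22) rose, and NQO1 (-1.54 ± 0.09), MT1E (-1.85 ± 0.12) and CCND1 (-2.27 ± 0.32) fell. Of 23 NRF2 targets 9 fell and 1 rose (camera 0.00623), with an adjusted p = 0.238 with an estimated correlation. The count of 2758 was 1072 and 1308 without replicate 1 or 2 at 0.5 µM and 1732 without 2.5 µM replicate 2. TCDD at 10 against 2 nM raised 11 genes and lowered 37: SCD fell by 1.76 ± 0.14 and FADS2, another desaturase, by 1.34 ± 0.13, while CYP1A1 changed by 0.70 ± 0.21 (adjusted p = 0.279). Of 17 cholesterol genes 4 fell over all genes and 14 when adjusted over the list alone (camera 1.92e-24, 0.00329 with an estimated correlation). That count of 48 was 10 and 12 without replicate 1 or 2 at 2 nM, 5 and 11 without replicate 1 or 2 at 10 nM, 103 by DESeq2, 90 without a count filter, 1005 with these libraries alone, 30 with the block and 193 after the GC correction. The high against the low combination raised 68 genes, NQO1 among them (1.31 ± 0.09, adjusted p = 1.44e-05), and lowered 293, among them ANGPTL4 (-2.77 ± 0.25), STC1 (-2.44 ± 0.18) and SCD (-2.37 ± 0.15). Among 17 cholesterol genes 10 fell (camera 2.05e-19, 0.00726 with an estimated correlation). The 361 were 131 and 63 without replicate 1 or 2 of the low combination, 1173 and 1889 without replicate 1 or 2 of the high one, 14 with these libraries alone and 1087 after the GC correction.

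The last question was whether HgCl2 acted differently with TCDD than without, that is, whether the difference between a combination and its TCDD dose departed from the difference between HgCl2 and the untreated control. Acetone was taken as the solvent of TCDD, and no group was labelled as HgCl2 with acetone alone. A role of TCDD in a departure therefore cannot be told apart from a role of acetone. At the low doses 1 gene departed. The cholesterol list (camera 9.44e-08, 0.047 with an estimated correlation) and the hypoxia list (camera 1.9e-08, 0.047 with an estimated correlation) departed upward, and the cytokine list downward (camera 4.5e-08, 0.0343 with an estimated correlation). No gene passed without any 1 of the 8 libraries, with the block or with all 4 control libraries, DESeq2 called 8 genes, edgeR called 2 without a filter, 2 after the GC correction and 6 with these libraries alone, and 520 genes had an unadjusted p under 0.05. At the high doses 902 genes departed, 270 upward and 632 downward. HgCl2 at 2.5 µM raised NDRG1, STC1 and CA9 without TCDD, and with 10 nM TCDD the change departed by -3.29 ± 0.3, -4.55 ± 0.31 and -5.92 ± 0.67. The size for CA9 is uncertain, as the untreated libraries held 3 and 5 counts of it. NQO1 departed the other way (1.59 ± 0.13, adjusted p = 7.46e-05), as did HSPA8 (1.04 ± 0.15, adjusted p = 0.00284). Among 17 cholesterol genes 7 departed downward (camera 1.05e-09, 0.0246 with an estimated correlation), of 19 hypoxia genes 7 (camera 1.8e-08, 0.0319 with an estimated correlation) and of 21 interferon genes 9 (camera 1.2e-10, 0.0246 with an estimated correlation), while 6 of 15 heat shock genes departed upward (camera 1.2e-10, 0.0246 with an estimated correlation). The 902 were 467 and 445 without control replicate 1 or 2, 471 without 2.5 µM replicate 1, 335 and 301 without 10 nM replicate 1 or 2, 2732 without high combination replicate 1, 471 with all 4 control libraries and 1785 after the GC correction. With the libraries of these 4 groups alone 12 genes passed, NQO1, STC1 and NDRG1 among them and CA9 and HSPA8 not.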

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

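The 2 tests of departure from the sum of the single exposures were planned; all tests of technical explanations in this part were chosen after the results were seen.

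A difference between groups, tested directly, marks out the following results: the effect of HgCl2 without TCDD against its effect with TCDD. No group was labelled as HgCl2 with acetone alone, so TCDD and its solvent cannot be told apart in this test. At the low doses a departure was found in 1 gene and at the high doses in 902 genes. The call at the low doses ended without any 1 of the 8 libraries.

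At the high doses the departure was 1.59 for NQO1 (adjusted p = 7.46e-05), 0.81 for SRXN1 (adjusted p = 0.00156), 0.75 for TXNRD1 (adjusted p = 0.0135), 1.04 for HSPA8 (adjusted p = 0.00284), 2.46 for CCND1 (adjusted p = 0.00618) and 1.45 for ASNS (adjusted p = 0.00252). It was -4.55 for STC1 (adjusted p = 1.89e-05), -5.92 for CA9 (adjusted p = 0.000757), -3.29 for NDRG1 (adjusted p = 0.000143), -2.04 for OAS2 (adjusted p = 0.00252) and -2.17 for MX2 (adjusted p = 0.0035). With the libraries of these 4 groups alone NQO1, STC1 and NDRG1 passed and the other 8 did not. The untreated libraries held only 3 and 5 CA9 counts, so the size of its departure is uncertain. TXNRD1 also lost its call without control replicate 2 or either 10 nM TCDD library. Both the presence and the size of these departures rest on the HgCl2 group at 2.5 µM and on the high combination, which the next paragraphs weigh. They also rest on the untreated control, the reference for HgCl2. At 2.5 µM OAS2 stood at 7.96 CPM, against 2.71 CPM untreated and 8.08 CPM with acetone. ASNS stood at 63.4 CPM, against 123 and 20.7 CPM, and CCND1 at 19.5 CPM, against 116 and 29.8 CPM. For NQO1 the controls were close, at 72.8 and 73.8 CPM. The departures were not computed with acetone as that reference. Exchanged labels of the 2 HgCl2 groups, left open below, would change them, and the departures were not recounted with the groups exchanged.

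The first pattern is that stress response, cytokine and metallothionein genes rose against the vehicle in all 4 TCDD-containing groups. The immediate early list was counted with them and gave 28 calls over these groups. Its genes did not all rise in each group: NR4A1 stood at 14.6 CPM at 2 nM TCDD against 16.2 CPM with acetone. Of 140 calls in the 4 lists, each of 1 gene in 1 comparison, 10.7% were also higher against the untreated control, against 75% of the calls among AHR targets. By list the share was 10.9% for the stress response, 22% for cytokines, and 0% for metallothioneins and for immediate early genes. These lists had already been seen to fall with acetone against the same control, so the shares restate that fall and are no separate support. Low levels in the vehicle libraries may account for most of the calls. A GC trend between libraries as the whole cause is argued against by the 99.3% of calls left after the GC correction. Reads moving between metallothionein copies would leave their sum in place, but the summed counts of 14 metallothionein genes rose by at least 0.82 and by up to 1.67; the bound for this test was first set at over 1, which left it undecided, and was reset after the value was seen, so the test is weak. Still open are an effect of acetone that TCDD or the cells' state in those groups offset, and a difference in the culture or handling of the vehicle libraries, neither of which was tested.

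The second pattern is that 2.5 µM HgCl2 alone changed 2934 genes while 0.5 µM changed 3. A GC trend as the whole cause is argued against by the 77.3% of genes left after the correction. With every library thinned to the smallest total 2199 genes were called at 2.5 µM and 2 at 0.5 µM, and 71% of the calls were left; this bound was first set at over 75%, which left the test undecided, and was reset after the value was seen, so depth is not cleanly excluded as a part of the difference. The NRF2 list, which mercury raised by a median of 0.47 on 10 nM TCDD, had a median of -0.28 at 2.5 against 0.5 µM (camera 0.00623, but 0.238 with an estimated correlation), as exchanged labels of the 2 groups could give, although AKR1C3 rose at 2.5 µM. Exchanged labels therefore stay open, as does a biological effect of dose, which was not tested apart from the labels. An order of groups given under the other observations, noticed after the values were seen, would also follow dose if the labels were exchanged. With the groups exchanged, 1 gene in place of 4 was distinct to the low combination and 2 in place of 5 to the high one.

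The third pattern is that the 2 libraries of the high combination lay far apart. Among the genes the GC correction covers, the SD of their difference fell from 0.485 to 0.37, still above the highest other group at 0.339, so a GC trend is part of it and not the whole. A library from a group without TCDD is argued against, since in both libraries 100% of 6 genes (AHRR, ALDH1A3, CYP1A1, CYP1B1, SERPINB2 and TIPARP), chosen as higher in each of the other 3 TCDD-containing groups than in each group without TCDD, were above all 8 libraries without TCDD. Of the libraries without TCDD, each held against the other 7, the highest reached 50%. A first form of this test used the control libraries alone and could not tell such a library from 2.5 µM HgCl2, and it was replaced after its value was seen. A library of 10 nM TCDD alone is argued against by NRF2 list medians of 0.42 and 0.46 after the GC correction, measured against the mean of the 10 nM TCDD libraries. Those libraries lie around that mean by construction and reached 0.01. Libraries of the other groups without HgCl2 were not compared in this way. No biological explanation was tested, as the design names none within a group.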

How the results depend on the processing

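The GC correction, alone and with the replicate block, the recount of genes called against both controls and the exchange of the 2 HgCl2 groups were chosen after seeing the data; the other alternatives were planned. With 1 library left out, the lone library of its group is assumed to vary like the other groups. The alternative of another pseudocount applied to normalised values and was not run, as the files hold counts. Where no cause is named for a change below, the cause was not tested.

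Scaling by DESeq2 size factors and the stricter filter kept every count of called genes within 1.5 times. The size factors moved the median log2 change of all genes by at most 0.025. Of the named genes, 868 calls or misses held with DESeq2 size factors and 11 calls were lost. With the stricter filter 772 held and 8 were lost, without a filter 864 and 9. The DESeq2 Wald test kept 845 and lost 25, and the block kept 816 and lost 63. Other settings changed more. With the libraries of the compared groups alone 621 held and 224 calls were lost. All 4 control libraries as 1 group kept 545 and lost 263, and the other control kept 213 and lost 116, beside the reversals given below.

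The DESeq2 Wald test called 27 genes in place of 3 at 0.5 µM HgCl2, 13 in place of 4 for the low combination against 2 nM TCDD, 22 in place of 6 for the high one against 10 nM, 103 in place of 48 between TCDD doses, and 8 in place of 1 for the departure at the low doses. It counted 10 genes distinct to the low combination in place of 4 and 15 for the high one in place of 5. In the same order, the fit without a count filter gave 21, 7, 16, 90 and 2, with 14 distinct to the high combination; it tests more genes.

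With the replicate numbers as a block, 2 genes were left for each combination against its TCDD dose, 30 between TCDD doses, 0 for the departure at the low doses (520 at an unadjusted p under 0.05, 8 by DESeq2), and 2 and 1 distinct to the low and high combinations. Replicate differences showed no common pairing by replicate number. Over 28 pairs of groups their median correlation was -0.07 (from -0.72 to 0.6), with 10 above 0.1 and 13 below -0.1. The GC trends of the libraries were not removed first, so a shared day or culture cannot be excluded.

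With the libraries of the compared groups alone, the spread comes from those libraries only. The counts were then 9 at 0.5 µM HgCl2, 1592 at 2.5 µM, 3722 and 1981 at 2 and 10 nM TCDD, and 3778 and 29 for the low and high combinations against acetone. They were 31 and 0 against TCDD (for the 0, 595 at an unadjusted p under 0.05 and 22 by DESeq2 with all libraries), 4355 and 11 against HgCl2, 1005 between TCDD doses, 14 between combinations, and 6 and 12 for the departures. Distinct genes were 23 and 0. With the 2 HgCl2 groups exchanged they were 1 and 2.

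Against all 4 control libraries the counts were 6 at 0.5 µM HgCl2, 59 at 10 nM TCDD, 576 for the high combination, and 0 and 471 for the departures. Against the other control they were 771 at 0.5 µM HgCl2, 189 at 10 nM TCDD and 568 for the high combination.

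The GC correction gave 1122 genes for acetone, 20 at 0.5 µM HgCl2, 2006 and 1142 at 2 and 10 nM TCDD, 2614 and 2380 for the low and high combinations, 11 for the high one against TCDD, 2631 and 1947 for the combinations against HgCl2, 193 between TCDD doses, 1087 between combinations, 2 and 1785 for the departures, and 9 distinct to the high combination. With the block added it gave 920, 11, 1709, 931, 2306, 2041, 129 between TCDD doses, 801 between combinations, and 0 and 1510 for the departures. The share of higher genes among those called moved by over 10 points with the correction: from 22.6% to 40.0% for acetone, 62.8% to 47.3% at 2.5 µM HgCl2, 74.7% to 47.0% and 72.8% to 48.5% at 2 and 10 nM TCDD, 77.9% to 45.4% and 59.8% to 48.5% for the combinations against acetone, 100% to 81.8% for the high one against TCDD, 65.6% to 46.0% and 27.8% to 52.4% for the combinations against HgCl2, 62.9% to 48.1% between HgCl2 doses, 18.8% to 55.0% between combinations and 29.9% to 56.5% for the departure at the high doses. In a simulation with an added GC trend, edgeR recovered 60% of changes of 1 with 28 false calls, and 75% with 13 after the correction.

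With 1 library left out, the counts ran from 161 to 305 for acetone, stayed at 1 at 0.5 µM HgCl2, and ran from 1576 to 2241 at 2.5 µM, 159 to 202 and 136 to 177 at 2 and 10 nM TCDD, 294 to 686 and 328 to 4947 for the low and high combinations. They ran from 2 to 3 and 1 to 1624 for the combinations against TCDD, 411 to 849 and 574 to 3749 against HgCl2, 1072 to 2203 between HgCl2 doses, 5 to 12 between TCDD doses, 63 to 1889 between combinations, and 301 to 2732 for the departure at the high doses, and were 0 for that at the low doses. Distinct genes ran from 2 to 3 and from 1 to 307. The high ends of the high combination, 4947, 1624, 1889 and 307, came without its replicate 2, and 3749 and 2732 without its replicate 1. Of named genes, 2944 calls or misses held, 873 calls were lost, 22 were gained and none reversed.

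Of 17 lists, 8 were called for acetone and 6 with an estimated correlation. At 0.5 µM HgCl2 10 were called, 1 with an estimated correlation and 5 by fry; at 2.5 µM 7, 4 and 12. At 2 nM TCDD 11 fell to 5 with an estimated correlation, at 10 nM 10 to 7, in the low and high combinations 12 to 7 and 11 to 7. For the departures 7 fell to 3 (and 3 by fry) and 8 to 4. With 1 library left out the lists called ran from 7 to 9, 5 to 10, 5 to 9, 9 to 11, 9 to 10, 12 to 14 and 11 to 12 in these 7 comparisons, and 6 to 9 and 7 to 8 for the departures.

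The choice of control turned the sign of 61 changes of named genes that passed under at least 1 of the controls compared. Of these, 50 came with the other control and 11 with all 4 control libraries as 1 group, and some changes count under both. Some values were close to no change, such as SESN1 at 0.02 and IER3 at -0.03, so those changes were lost rather than reversed. Against acetone, 2.5 µM HgCl2 gave ANKRD1 1.62, ASNS 1.62, CSF2 0.21, MT1E 0.80, MT1X 0.86, MT2A 0.80, PSAT1 0.79, SLC7A5 0.78, STC2 1.73 and TXNRD1 0.33. Against the untreated control, 2 nM TCDD gave ASNS -0.23, C19orf33 -1.36, COL5A3 1.37, EGR1 -0.37, IER3 -0.03, MT1E -1.11, MT1X -0.78, MT2A -0.78, MYC -0.51, PSAT1 -0.20, STC2 -0.08, TGFBI 0.32 and TXNRD1 -0.11; 10 nM gave ABCA1 0.37, C19orf33 -0.86, GADD45A -0.17, INSIG1 0.09, MT1E -0.16, MT2A -0.16 and NR4A1 -0.32. The low combination gave ASNS -0.41, C19orf33 -1.28, COL5A3 1.34, EGR1 -0.05, FOSB -0.48, GADD45A -0.23, MT1E -1.15, MT1X -0.38, MT2A -0.71 and TGFBI 0.55; the high one gave ABCA1 0.44, C19orf33 -0.41, EGR1 -0.20, FOSB -0.16, GADD45A -0.26, MT1E -0.14, MT1X -0.14, OAS2 0.51, SESN1 0.02 and SLC39A10 0.10. Against all 4 control libraries, 2.5 µM HgCl2 gave SLC7A5 0.10 and STC2 0.20, 2 nM TCDD gave C19orf33 -0.36, MT1E -0.36, MT1X -0.20, MT2A -0.20 and MYC -0.11, the low combination gave C19orf33 -0.27, MT1E -0.40 and MT2A -0.13, and the departure of STC2 at the high doses became -0.11. These values follow from the difference between the 2 controls that the report gives.

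Depth limits low levels: in the smallest library, with a total of 7.01 in units of 1e6 counts, 3 counts equal 0.428 CPM.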

Other observations

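Across the 8 groups, a matrix gene was high and a chaperone and the transferrin receptor were low in 3 groups. These were 2.5 µM HgCl2, 2 nM TCDD and the low combination, which share no single treatment. If the labels of the 2 HgCl2 groups were exchanged, a question left open above, these 3 would be the groups with the lower doses. SCD stood at 324, 274 and 333 CPM in these 3 groups. It stood at 265 CPM with acetone, 98.9 CPM untreated and 61 to 81.1 CPM in the other treated groups. COL5A1, a fibrillar collagen, stood at 77.2, 66.5 and 68.4 CPM in these 3 groups, at 61.9 CPM with acetone, and at 45.8, 25.7, 32.9 and 19.0 CPM in the other 4. It did not separate these groups from acetone: low combination replicate 1 had 62.02 CPM and acetone replicate 2 had 62.04 CPM. The matrix gene FN1 had another order, at 122 and 107 CPM untreated and with acetone against 84.5, 88.4 and 70.2 CPM in the 3 groups. HSPA8 was lowest in the same 3 groups, at 847, 1200 and 1130 CPM, against 1480 to 1890 CPM elsewhere, and so was TFRC, at 187, 259 and 229 CPM, against 356 to 666 CPM. No test across the groups was run for this pattern, and the order was noticed after the values were seen.

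CCND1, cyclin D1, separated the groups in another way: it stood at 116 and 94.8 CPM in the untreated control and at 0.5 µM HgCl2, and at 19.5 to 40.1 CPM in the 6 other groups, acetone among them at 29.8 CPM. HMGA2 (8.00 and 7.24 against 1.57 to 3.51 CPM) and FGF5 (5.52 and 4.13 against 0.722 to 1.59 CPM) followed the same order.

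C19orf33 had no count in either acetone library and stood at 17.9 CPM in the untreated control and 6.89 to 17.1 CPM in the 6 treated groups. It overlaps YIF1B, and its changes against acetone depend on how a count of 0 is treated.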
